A study of Mus musculus with 12 samples.

How the data were processed

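The samples were mouse embryonic fibroblasts (MEFs) of the C57BL/6 background, either wild type or deficient in XBP1, a transcription factor of the unfolded protein response whose mRNA is spliced by the endoplasmic reticulum sensor IRE1. Tunicamycin blocks N-linked glycosylation, so that unfolded proteins accumulate in the endoplasmic reticulum. Cells were left untreated or were treated with 2 ug/mL tunicamycin for 12 h or 24 h. Per the labels' protocols, total RNA was labelled directly with the dye Cy3 and hybridised to 1-colour Agilent microRNA arrays. There were 12 arrays in 6 groups of 2, and the labels describe the replicates of a group as separate experiments. The number of arrays limits the precision of every value given here.

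The deposited scanner files hold spot intensity values made with Agilent Feature Extraction 10.7.1.1, per the file headers. Per the file headers, the processed intensity of a spot is its signal after background subtraction and spatial detrending, with no normalization between arrays. The software also writes 1 total signal and 1 detection call per miRNA and array. The series table holds the authors' log2 values per miRNA and array. Those log2 values, as the authors deposited them, equalled the log2 of the software's total gene signal to within 1.15e-06 on every array, with missing values in the same places, so they too were not normalized between arrays. Column medians of that table ran from 5.38 in the first replicate of wild type at 24 h to 7.45 in the second replicate of untreated knockout. Any further step of the authors, such as the rule by which they extracted miRNAs, is not given in the sources used here.

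Signals were recomputed from the spots. Control spots and spots that the software called outliers were left out. The processed signals of a probe's spots were averaged, and the probe means were summed over the probes of a miRNA. The arrays carried 13000 spots that were not controls, for 1857 probes and 650 miRNAs, of which 611 were from mouse and 39 were viral. A probe had between 5 and 20 spots, and a miRNA between 1 and 4 probes. No spot was saturated. Each array was scaled so that its 75th percentile over the 95 mouse miRNAs detected on all 12 arrays was equal. Scaled signals under the 5th percentile of the detected ones, a value of 10.0 (3.33 on the log2 scale), were set to that floor, and log2 was taken. A miRNA was tested where the software called it detected on both arrays of at least 1 group, which held for 256 mouse miRNAs. Of these, 110 were above the floor on every array and 18 were at the floor on every array. Where no array of a group detected a miRNA, the difference is given as a bound ("at least N-fold"). The bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest scaled signal among detected miRNAs and the miRNA's own signal. Values set to the floor have no spread, so standard errors of miRNAs near the floor are too small.

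Tests were made with limma 3.58.1 in R 4.3.3, with the package data.table, version 1.17.8, for reading the files, and plots with matplotlib 3.10.9 in Python 3.11.15. A single model with 1 mean per group was fitted to all 12 arrays (lmFit, contrasts.fit, eBayes with an intensity trend), with 6 residual degrees of freedom and a prior worth 0.981. In each of 11 comparisons p-values were adjusted by the Benjamini-Hochberg method, and a miRNA was past the threshold at an adjusted p under 0.05. The comparisons were tunicamycin against untreated at 12 h and at 24 h in each genotype, the difference between the genotypes' responses at each time, 24 h against 12 h, and knockout against wild type in each condition and over all conditions. Values are log2 differences with the standard error (SE) of the fit, each group having 2 arrays.

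Before the data were examined, 30 lists of miRNAs were fixed, covering unfolded-protein-response links, seed families, genomic clusters, passenger strands and markers of cell types. In each comparison the 25 lists with at least 2 tested members were tested with limma's camera, with a preset correlation between miRNAs of 0.01 and again with an estimated correlation, adjusted over the lists. None of the epithelial or endothelial markers on the array was among the tested miRNAs, and a single member was tested of the muscle markers (miR-206), the hypoxia marker list (miR-210) and the miR-143~145 cluster (miR-143). The miRNAs named in the text were also chosen by a rule fixed beforehand. They are, among miRNAs past the threshold and detected on both arrays of at least 1 compared group, the 10 with the largest rise and the 10 with the largest fall, up to 4 members of a list with the smallest p-values, and every miRNA past the threshold both in wild type at 12 h and in the difference between genotypes at 12 h. Of the 256 tested miRNAs, 233 matched a gene name in a reference table of the assembly GRCm38.p6. The files name no genome build, so no coordinates are given, and names are those of the array design.

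The file headers and the labels place the 12 arrays on 2 slides and in 4 scans. The untreated arrays were on slide 1, with replicate 1 in scan 1 and replicate 2 in scan 2. All tunicamycin arrays were on slide 2, with replicate 1 in scan 3 and replicate 2 in scan 4. Slide and tunicamycin therefore cannot be told apart, whereas each scan held both genotypes, and scans 3 and 4 held both times. Wild type lay in row 1 and knockout in row 2 of every slide. On slide 2 the 12 h arrays lay in columns 1 and 4 and the 24 h arrays in columns 2 and 3. Time after tunicamycin and array column therefore cannot be told apart. Whether equal replicate numbers pair the arrays was checked by correlating, over the 110 miRNAs above the floor, the deviations of same-numbered arrays from their group means. The correlation between genotypes was 0.880 untreated, 0.587 at 12 h and 0.440 at 24 h, and these pairs share a scan. Between tunicamycin and untreated arrays of 1 genotype, which do not share a scan, it was 0.014 and 0.240 at 12 h for wild type and knockout, and -0.521 and -0.447 at 24 h. Between 12 h and 24 h it was 0.094 in wild type and 0.016 in knockout. The main fit had no block. Scan was therefore used in alternative fits, as a block for comparisons within scans and as a random block for tunicamycin against untreated.

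The procedure was tested on simulated data in which 40 of the 256 miRNAs were changed, over 20 runs. The noise was independent between miRNAs and arrays, with spreads drawn from miRNAs above the floor on every array. For 12 h tunicamycin in wild type, 39.8% of miRNAs changed by a log2 of 1 and 72.8% of those changed by a log2 of 2 were recovered, and 8.91% of the calls were false. For the difference between genotypes at 12 h the recovered shares were 16.5% and 53.5%, and 9.97% of the calls were false. A list of 29 miRNAs shifted by a log2 of 2 passed camera in 20 of 20 runs, and unshifted in 0 of 20, both in the wild type comparison and in the difference between the genotypes' responses. As the simulated miRNAs did not vary together, these runs do not test the preset correlation between miRNAs. Smaller lists and shifts were not simulated. Alternatives fixed beforehand were normexp background correction, quantile normalization, a percentile over all mouse miRNAs, the software's total gene signal, the mean of probe log2 values, other filters and another floor, the authors' deposited values, each array left out in turn, blocks for replicate and scan, and a fit without the intensity trend. The files hold no mean spot signal, so normexp used the median signals. The alternatives chosen after seeing the data were leaving values at the floor out, using the floor as a pseudocount, keeping outlier spots, leaving out the 12 h arrays, and a block with crossed replicate numbers. No column of sample values was left unused for want of a mapping. The mRNA of Xbp1 is not measured on these arrays, so the genotype labels could not be checked from it.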

Results

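MicroRNA levels were measured in wild type and XBP1-deficient MEFs that were untreated or had received 2 ug/mL tunicamycin for 12 h or 24 h. Each of the 6 groups had 2 arrays. The total unscaled signal of the mouse miRNAs was 94800 and 108000 on the untreated wild type arrays and 184000 and 186000 on the untreated knockout arrays. At 12 h it was 32300 and 67400 in wild type and 40300 and 78200 in knockout, and at 24 h it was 14100 and 32700 in wild type and 35500 and 41900 in knockout. The number of mouse miRNAs detected was lowest, at 120, on the first wild type array at 24 h. Every tunicamycin array thus had a lower total than every untreated array, and the differences below are between scaled signals. The design asks which miRNAs respond to 12 h of tunicamycin in a manner that depends on XBP1.

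The first comparison asked which miRNAs changed after 12 h of tunicamycin in wild type cells. Most of the largest rises were in miRNAs at the floor on at least 1 untreated array, with miR-877* and miR-574-3p above it on both. miR-207 was at least 172-fold higher (log2 difference 7.42, SE 1.48, limma adjusted p = 0.00561), miR-1196 at least 108-fold (6.75, SE 1.39) and miR-197 at least 98.4-fold (6.62, SE 1.27). miR-877* rose by 6.91 (SE 1.23), miR-574-3p by 5.93 (SE 1.82) and miR-468 by 5.78 (SE 0.97), and miR-1894-5p was at least 64.9-fold higher (6.02, SE 1.18). Binding of labelled RNA to probes without a matching miRNA, raised below from viral probes, was not tested for these rises. The largest falls were in miR-146b (-2.68, SE 0.41, limma adjusted p = 0.00203), miR-361 (at least 4.66-fold lower, -2.66, SE 0.24), miR-152 (at least 4.43-fold lower, -2.29, SE 0.16), miR-146a (at least 3.86-fold lower, -2.19, SE 0.51) and miR-362-5p (-2.06, SE 0.33). The miR-146 miRNAs are induced by NF-kB and dampen innate immune signalling. miR-378 (-1.99, SE 0.28), miR-322 (-1.91, SE 0.32), miR-101a (at least 2.54-fold lower) and miR-362-3p (at least 3.31-fold lower) fell as well. miR-322 is a member of the miR-15/16 seed family, which restrains the cell cycle. With normexp background correction the values of miR-361, miR-152, miR-146a, miR-362-5p, miR-378, miR-101a and miR-362-3p turned positive, and with the total gene signal that of miR-146b did (0.22).

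A group that moved together was the large miRNA cluster in an intron of Sfmbt2, a Polycomb-related gene, which holds the rodent miR-297, miR-466, miR-467 and miR-669 families. Of its 29 tested members, 22 rose and 2 fell at 12 h in wild type, and 23 and 2 adjusted over the list alone, with a median log2 difference of 3.59. miR-466d-3p was 5.00 (SE 0.40) above the floor, where both untreated arrays lay, so the size of its rise is limited by the floor. miR-669h-3p was at least 77.7-fold higher (6.28, SE 1.45), miR-669i at least 19.8-fold (4.31, SE 0.36), miR-466j at least 12.0-fold (3.59, SE 0.33) and miR-466l at least 8.02-fold, and such members entered the median with the floor in place of their untreated level. miR-467b* rose by 6.40 (SE 1.74) and miR-467g by 6.25 (SE 1.67). Some members already varied between the 2 untreated wild type arrays. The log2 standard deviation (SD) there was 1.12 for miR-467b*, against 0.0884 for miR-467a*. The members that fell were miR-467a (-1.93, SE 0.44) and miR-467b (-1.49, SE 0.33), although miR-467a* and miR-467b* from the same precursors rose, and miR-467a turned positive (0.50) under normexp. In limma's camera the list passed with the preset correlation (adjusted p = 2.56e-05), with adjusted p = 0.670 with an estimated correlation. The median stayed positive over all 13 alternatives tried on the list, from 1.06 among miRNAs detected on all arrays to 4.34. It was 1.99 under normexp, which moved the median of all tested miRNAs up by 1.32.

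**Figure D1:**
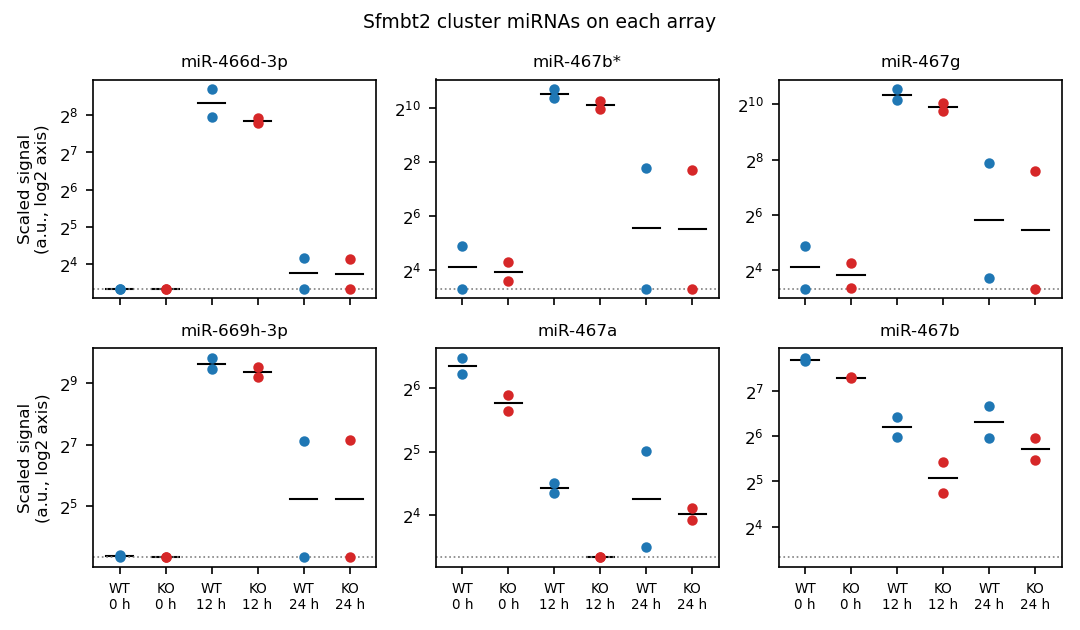
Scaled signal (arbitrary units, log2 axis) of 6 miRNAs of the Sfmbt2 cluster on each array, wild type in blue and knockout in red, untreated (0 h), 12 h and 24 h. Points are arrays, black bars geometric means of 2 arrays and the dotted line the floor of 10.0. miR-466d-3p, miR-467b*, miR-467g and miR-669h-3p rise at 12 h in both genotypes and are lower at 24 h, whereas miR-467a and miR-467b are lower at 12 h in both, a direction that turns for miR-467a under normexp.

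Passenger strands, the arms named with an asterisk, also shifted at 12 h in wild type, with 16 of 35 higher and 2 lower (16 and 2 adjusted over the list alone), a median of 0.59 and a camera adjusted p = 0.0141, against adjusted p = 0.670 with an estimated correlation. That median was 1.55 under normexp, 0.00 under quantile normalization and -0.04 among miRNAs detected on all arrays. Of 3 tested miRNAs linked to cleavage by IRE1, miR-125b-5p (-0.88, SE 0.15, limma adjusted p = 0.00312) and miR-96 (-0.60, SE 0.21, limma adjusted p = 0.0470) fell, though miR-96 turned positive under normexp (0.12), and miR-34a differed by 0.05 (SE 0.31). The list of 3 did not pass camera (adjusted p = 0.450). A list fixed beforehand for links to the sensors PERK and ATF6 or to CHOP had 7 tested members, of which 3 rose and 2 fell (camera adjusted p = 0.821). Which sensor each member is linked to was not checked here. miR-346, described as induced in endoplasmic reticulum stress, was at least 42.2-fold higher (5.40, SE 1.11, limma adjusted p = 0.00602). miR-211, described as induced through PERK, was at least 12.4-fold higher (3.63, SE 0.52). Probes for 2 viral miRNAs rose at 12 h too, as given below. Binding without a matching miRNA was not tested for miR-346 and miR-211, so their rises may not be induction. Among fibroblast and mesenchymal markers 7 of 11 fell (median -0.60, camera adjusted p = 0.0753), and the median stayed negative under each of the 3 other scalings. Over all miRNAs detected on every array the median was -0.42. The miR-30 family had 4 of 5 members lower (median -0.75, camera adjusted p = 0.139), a median that turned to 0.48 under normexp.

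In all, 130 of 256 miRNAs passed in wild type at 12 h, 65 higher and 65 lower, with 140 at an unadjusted p under 0.05. Of the 151 above the floor on all 4 arrays, 19 rose and 49 fell. The direction of the count depended on the scaling, with 55 higher and 105 lower under quantile normalization and 181 higher and 11 lower under normexp, which moved the median of all tested miRNAs by 1.32. Untreated and tunicamycin arrays were on different slides, so slide and treatment cannot be told apart, and without the second untreated wild type array 85 miRNAs passed. With scan as a random block 131 passed.

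The same comparison in XBP1 knockout cells asked which changes arise without XBP1. miR-207 rose by 6.98 (SE 1.48, limma adjusted p = 0.00710), miR-877* by 6.54 (SE 1.23) and miR-467b* by 6.15 (SE 1.74), while miR-1196 was at least 83.7-fold higher (6.39, SE 1.39) and miR-197 at least 76.5-fold (6.26, SE 1.27). miR-346 was at least 43.5-fold higher (5.44, SE 1.11) and miR-211 at least 11.7-fold (3.55, SE 0.52). The largest fall was again in miR-146b (-4.19, SE 0.41, limma adjusted p = 0.000328). It was followed by miR-497 (at least 7.35-fold lower, -2.92, SE 0.23), miR-322 (-2.88, SE 0.32), miR-210 (-2.81, SE 0.11), miR-195 (at least 6.15-fold lower, -2.66, SE 0.22) and miR-503 (at least 3.99-fold lower, -2.04, SE 0.11). miR-210 is induced by hypoxia-inducible factors, and miR-497 and miR-195 are made from 1 cluster of the miR-15/16 family. Under normexp the values of miR-497 (0.10), miR-195 (0.24) and miR-503 (0.46) turned positive, while those of miR-322 (-1.82) and miR-210 (-0.25) stayed negative. miR-218, miR-152 (at least 5.09-fold lower), miR-467a (at least 5.28-fold lower) and miR-467b (-2.21, SE 0.33) fell too, and miR-218, miR-152 and miR-467a turned positive under normexp.

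The Sfmbt2 cluster moved in knockout cells as well, with 21 of 29 members higher and 2 lower (23 and 3 adjusted over the list alone), a median of 3.58 (1.33 to 4.08 over the alternatives), a camera adjusted p = 2.56e-05 and adjusted p = 0.634 with an estimated correlation. The next calls were all lost with an estimated correlation (adjusted p = 0.634 for each). The miR-15/16 family had 5 of 6 members lower (6 adjusted over the list alone, median -1.75, camera adjusted p = 0.0178), a median that stayed negative under normexp (-0.46). The miR-30 family had 5 of 5 lower (median -1.03, adjusted p = 0.0393), turning to 0.11 under normexp, and the cluster of miR-322 and miR-503 4 of 6 (median -0.57, adjusted p = 0.0393), turning to 1.03. Fibroblast and mesenchymal markers had 8 of 11 lower (median -0.96, adjusted p = 0.0232), among them miR-199a-5p (-1.76, SE 0.29), miR-143 (-1.99, SE 0.28) and miR-22 (-0.75, SE 0.14), and passenger strands had 15 of 35 higher and 2 lower (median 0.94, adjusted p = 0.0178). The median of the fibroblast markers ran from -1.80 to -0.35 over the 13 alternatives, 3 of which lost the call, and that of the passenger strands from 0.00 to 1.41, with the call lost in 5. Over all miRNAs detected on every array the median was -0.44 in knockout cells. Among blood-cell markers miR-155, an immune regulator, rose by 0.97, and it was at -0.03 under quantile normalization.

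In knockout cells at 12 h 126 miRNAs passed, 61 higher and 65 lower, with 147 at an unadjusted p under 0.05, and of the 149 above the floor on all 4 arrays 21 rose and 46 fell. The split was 58 higher and 105 lower under quantile normalization, 56 and 100 with a percentile over all miRNAs, and 164 and 19 under normexp. Of the 65 and 61 miRNAs that rose in wild type and knockout, 57 rose in both, where independent lists would share 15.5, and of 65 and 65 that fell, 49 fell in both, where independent lists would share 16.5. Of the 107 miRNAs past the threshold in both genotypes, 106 moved the same way. Across the 256 miRNAs, which are not independent replicates, the log2 differences of the genotypes had r = 0.954. These comparisons use separate untreated arrays, but the arrays of a replicate share scans. In both genotypes the tunicamycin arrays were also on another slide than the untreated arrays. A difference between slides would enter both comparisons alike, so the overlap and r cannot part it from a shared response to tunicamycin.

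**Figure D2:**
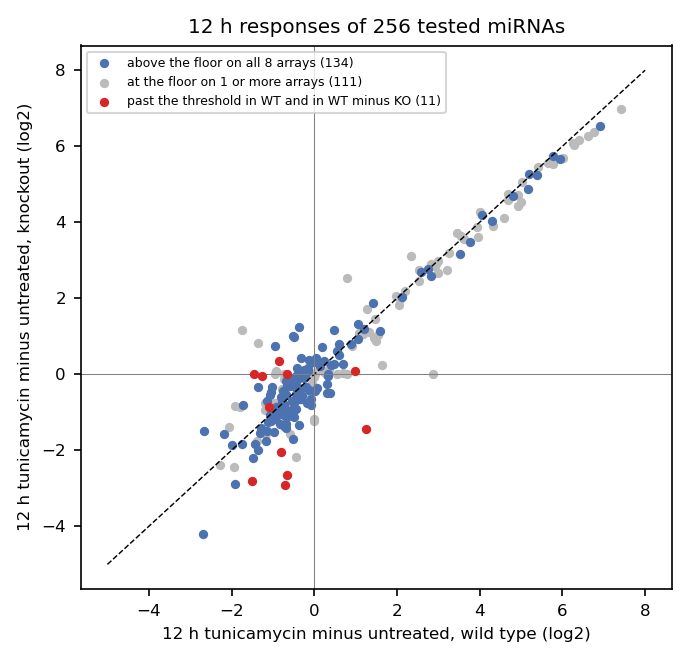
Log2 difference of 12 h tunicamycin minus untreated in wild type (x axis) and in XBP1 knockout (y axis) for the 256 tested miRNAs, each a point, with the dashed line at equal response. Blue points are miRNAs above the floor on all 8 arrays, grey points those at the floor on 1 or more, and red points the 11 miRNAs past the threshold in wild type and in wild type minus knockout. Most points lie near the line, with r = 0.954 across miRNAs.

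The comparison named in the design was the difference between the genotypes' 12 h responses, given as wild type minus knockout. miR-497 (2.22, SE 0.33, limma adjusted p = 0.0116) and miR-195 (2.01, SE 0.31) fell less in wild type than in knockout. The difference was also positive for miR-210 (1.31, SE 0.15, limma adjusted p = 0.00498) and miR-503 (1.23, SE 0.16), although miR-503 turned to -0.78 with the total gene signal. The responses of these 4 were -0.70, -0.65, -1.50 and -0.81 in wild type and -2.92, -2.66, -2.81 and -2.04 in knockout. Untreated knockout cells had more of all 4. At 12 h miR-210 and miR-503 were at the floor on both wild type arrays, and miR-497, miR-195 and miR-503 on both knockout arrays, so the size of those falls is limited by the floor, and which genotype had the larger fall of miR-210 or miR-503 cannot be read. miR-196b, from a Hox cluster, rose by 1.25 in wild type and fell by 1.45 in knockout (difference 2.70, SE 0.55, limma adjusted p = 0.0337), with wild type untreated arrays at the floor. miR-434-3p, at the floor on all untreated arrays, rose by 1.00 in wild type and differed by 0.09 in knockout (difference 0.91, SE 0.15). miR-335-5p (-1.46, SE 0.12, limma adjusted p = 0.000590), miR-532-5p (-1.21, SE 0.19), miR-532-3p (-0.67, SE 0.10), miR-290-5p (-1.20, SE 0.20) and miR-542-5p (-0.22, SE 0.04) had a negative difference. Of these 5, all but miR-532-3p turned positive under normexp, miR-335-5p to 0.34, miR-532-5p to 0.28, miR-290-5p to 0.063 and miR-542-5p to 0.15. miR-290-5p was also at 1.45 with the total gene signal. miR-542-5p was also positive under quantile normalization (0.088), a percentile over all miRNAs (0.17) and with outlier spots kept (0.052). The untreated knockout arrays were at the floor for miR-335-5p and miR-532-3p, where no fall could have been seen. For miR-503, miR-532-5p, miR-532-3p, miR-542-5p, miR-9 and miR-9* all 4 arrays at 12 h were at the floor, so the value is the difference between untreated genotypes and gives no direction of a response.

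These 11 miRNAs were past the threshold both in wild type at 12 h and in the difference, and 0 of the 11 were above the floor on all 8 arrays compared. Of the 134 miRNAs above the floor on all 8 arrays, 2 passed in the difference. miR-30a (0.63, SE 0.14, limma adjusted p = 0.0486) changed by -0.10 in wild type and by -0.73 in knockout, and miR-155 (-1.48, SE 0.30, limma adjusted p = 0.0337) by -0.50 in wild type and by 0.97 in knockout. miR-155 turned to 0.35 with the total gene signal and with the deposited values. miR-9 (1.17, SE 0.08) and miR-9* (1.24, SE 0.27), abundant in neural cells, were above the floor on the untreated knockout arrays and at it on the other 6 arrays. None of the 25 lists passed, and for the Sfmbt2 cluster the median difference was 0.15 (camera adjusted p = 0.885). The differences of miR-346 (-0.04, SE 1.57), miR-211 (0.08, SE 0.74) and miR-125b-5p (0.14, SE 0.22) were each smaller than the SE.

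For this difference 15 miRNAs passed, 9 positive and 6 negative, 6 of the 15 with all 12 h arrays at the floor, with 37 at an unadjusted p under 0.05, and 12 with scan as a block. The split was 9 and 5 under quantile normalization, 7 and 1 with a percentile over all miRNAs and 5 and 1 under normexp, and 7, 6 and 1 of those miRNAs were among the 15. With values at the floor left out 0 of 149 passed in limma, with 12 at an unadjusted p under 0.05, and 2 of the 15 were still among those tested. With 1 array left out the count was 5 without the first knockout array at 12 h, 23 without the first or the second knockout array at 24 h, and 31 without the first wild type array at 12 h.

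At 24 h in wild type cells the falls were larger in number than the rises. miR-146b (-3.34, SE 0.41, limma adjusted p = 0.00133), miR-322 (-2.15, SE 0.32) and miR-26a (-1.69, SE 0.22) fell. So did miR-378 (at least 7.05-fold lower), miR-152 (at least 4.26-fold), miR-361 (at least 4.11-fold), miR-146a (at least 3.84-fold), miR-143 (at least 2.82-fold) and miR-210 (at least 1.89-fold). These last 6 turned positive under normexp, and miR-146b turned to 0.27 with the deposited values. miR-31* (1.04, SE 0.13), miR-31 (0.66, SE 0.13), let-7e (0.81, SE 0.22), let-7b (0.68, SE 0.12) and miR-30a (0.43, SE 0.10) rose, and miR-194 was at least 10.6-fold higher (3.41, SE 0.72). The cluster of miR-322 and miR-503 had 4 of 6 members lower (median -0.68, camera adjusted p = 0.0246, adjusted p = 0.356 with an estimated correlation), a median that turned to 1.30 under normexp. The Sfmbt2 cluster had 0 higher and 3 lower of 29, with a median of 0.41 (camera adjusted p = 0.636). The 2 arrays stood apart, since the 22 members raised at 12 h had a median of 0.00 above untreated on the first and 1.22 on the second, where 11 stayed over 1 above it.

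In all 45 miRNAs passed at 24 h in wild type, 7 higher and 38 lower, with 77 at an unadjusted p under 0.05 and 45 with scan as a random block, and of the 141 above the floor on all 4 arrays 5 rose and 20 fell. Under normexp the split was 184 higher and 7 lower. The count was 16 with a percentile over all miRNAs, 26 and 24 without the first and the second untreated wild type array, and 75 and 77 without the first and the second knockout array at 24 h.

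In knockout cells at 24 h, miR-146b (-3.31, SE 0.41, limma adjusted p = 0.00226), miR-195 (at least 6.11-fold lower, -2.61, SE 0.22), miR-497 (-2.60, SE 0.23), miR-210 (-2.17, SE 0.11), miR-146a (-2.17, SE 0.51), miR-378 (-2.06, SE 0.28), miR-322 (-2.05, SE 0.32) and miR-503 (at least 4.10-fold lower, -2.04, SE 0.11) fell. Of these, miR-195, miR-497, miR-146a, miR-378 and miR-503 turned positive under normexp. Rises were seen in miR-196a (2.06, SE 0.53), miR-155 (1.33, SE 0.21), miR-720 (1.21, SE 0.22), miR-31* (0.91, SE 0.13), miR-23a (0.79, SE 0.19), miR-31 (0.73, SE 0.13), miR-25 (0.65, SE 0.15) and miR-24 (0.51, SE 0.09). The name miR-720 is thought to stand for a fragment of a tRNA. The cluster of miR-322 and miR-503 had 4 of 6 members lower (median -0.57, camera adjusted p = 0.00515, adjusted p = 0.210 with an estimated correlation), turning to 1.27 under normexp. The Sfmbt2 cluster had 0 higher and 3 lower, with a median of 0.27. Here too the arrays stood apart, the 21 members raised at 12 h having a median of -0.48 on the first and 1.39 on the second, where 12 stayed over 1 above untreated.

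In knockout cells at 24 h 36 miRNAs passed, 8 higher and 28 lower, with 57 at an unadjusted p under 0.05 and 36 with scan as a random block, and of the 134 above the floor on all 4 arrays 8 rose and 17 fell. The split was 1 and 15 with a percentile over all miRNAs and 178 and 10 under normexp. The count was 17 and 19 without the first and the second untreated knockout array, and 63 and 57 without the first and the second knockout array at 24 h.

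The difference between genotypes at 24 h, again wild type minus knockout, was led by miR-497 (2.22, SE 0.33, limma adjusted p = 0.0103), miR-195 (1.72, SE 0.31), miR-503 (1.23, SE 0.16) and miR-9 (1.17, SE 0.08) on the positive side. On the negative side were miR-155 (-1.49, SE 0.30), miR-532-5p (-1.45, SE 0.19), miR-152 (-1.40, SE 0.22), miR-335-5p (-1.35, SE 0.12) and miR-374 (-0.82, SE 0.11). miR-503 turned to -0.78 with the total gene signal and miR-335-5p to 0.11 under normexp. For miR-503, miR-532-3p, miR-542-5p and miR-9 all 4 arrays at 24 h were at the floor, so the value is the untreated difference. In total 12 passed, 5 positive and 7 negative, with 30 at an unadjusted p under 0.05 and 11 with scan as a block, and 2 of the 118 above the floor on all 8 arrays passed, miR-497 and miR-155. The untreated arrays enter both this difference and the one at 12 h, so the values of the 2 times are not independent. The split was 6 and 4 under quantile normalization, 5 and 4 with a percentile over all miRNAs and 1 and 1 under normexp, and 6, 6 and 0 of those miRNAs were among the 12. The count was 7 without the first or the second knockout array at 12 h, 44 without the first and 20 without the second knockout array at 24 h, and 3 with the 12 h arrays left out.

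The comparison of 24 h with 12 h, over both genotypes, asked how the response moved with time, within arrays that shared slide and scans. The 12 h and 24 h arrays lay in different array columns, so time and column cannot be told apart. The Sfmbt2 cluster fell back, with 25 of 29 members lower (26 adjusted over the list alone) and a median of -3.05 (camera adjusted p = 1.62e-09, adjusted p = 0.577 with an estimated correlation). miR-467b* fell by 4.77 (SE 1.23), miR-466d-3p by 4.36 (SE 0.28, limma adjusted p = 8.89e-05), miR-466j by 3.42 (SE 0.23) and miR-466l by 2.84 (SE 0.11), and the last 3 were detected on no array at 24 h, so that the floor limits their falls. Within scan 3 the median was -3.70 and within scan 4 it was -2.33, and under normexp it was -0.95. Other miRNAs raised at 12 h were lower at 24 h, among them miR-197 (-4.79, SE 0.89), miR-207 (-4.36, SE 1.05), miR-1894-5p (-4.33, SE 0.84), miR-485* (-4.32, SE 0.71), miR-1196 (-4.18, SE 0.98) and miR-346 (-4.01, SE 0.78).

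The let-7 family, which promotes differentiation, had 8 of 9 members higher at 24 h than at 12 h (median 0.57, camera adjusted p = 0.00500, adjusted p = 0.639 with an estimated correlation), among them let-7g (0.68, SE 0.13) and let-7b (0.40, SE 0.08). Its median was 0.42 within scan 3 and 0.73 within scan 4. Fibroblast and mesenchymal markers had 8 of 11 higher (median 0.47, camera adjusted p = 0.00500, adjusted p = 0.577 with an estimated correlation). Within scans 3 and 4 their median was 0.34 and 0.55, and both lists kept a positive median under the 3 other scalings. Over all miRNAs detected on every array the median was 0.42, which is near the medians of both lists. All 3 tested members of the miR-106b~25 cluster rose, miR-25 by 0.75 (SE 0.10), miR-106b by 0.75 (SE 0.16) and miR-93 by 0.49 (SE 0.08), though the cluster did not pass camera (adjusted p = 0.0556). miR-362-5p (0.94, SE 0.23), miR-148a (0.92, SE 0.24) and miR-100 (0.93, SE 0.25) also rose, miR-100 turning to -1.48 with the total gene signal.

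Between 24 h and 12 h 118 miRNAs passed, 50 higher and 68 lower, with 132 at an unadjusted p under 0.05 and 111 with scan as a block. Of the 112 above the floor on all 8 arrays, 45 rose and 12 fell. The split was 103 and 60 under quantile normalization, 103 and 62 with a percentile over all miRNAs and 14 and 35 under normexp. Without the second knockout array at 12 h 78 passed.

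Untreated knockout cells were compared with untreated wild type cells to find differences present before tunicamycin. miR-196b was at least 21.3-fold higher in knockout (4.42, SE 0.39, limma adjusted p = 0.000337), followed by miR-210 (2.02, SE 0.11), miR-199b* (2.02, SE 0.21), miR-221 (1.32, SE 0.26), miR-322 (1.32, SE 0.32), miR-195 (1.29, SE 0.22), miR-503 (1.23, SE 0.11) and miR-497 (1.18, SE 0.23). miR-9* and miR-9 were at least 2.36-fold and 2.24-fold higher. Lower in knockout were miR-155 (-2.82, SE 0.21, limma adjusted p = 0.000156), miR-224 (-2.01, SE 0.28, knockout arrays at the floor), miR-31 (-1.66, SE 0.13), miR-31* (-1.65, SE 0.13), miR-129-5p (-1.66, SE 0.33), miR-129-3p (-1.38, SE 0.24), miR-362-3p (-1.46, SE 0.25), miR-362-5p (-1.43, SE 0.33) and miR-500 (-1.24, SE 0.24), and miR-335-5p was at least 2.80-fold lower. Within scans 1 and 2, miR-155 differed by -2.77 and -2.86, miR-31 by -1.74 and -1.59, and miR-210 by 1.98 and 2.06.

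In this comparison 32 miRNAs passed, 13 higher and 19 lower in knockout, with 54 at an unadjusted p under 0.05 and 35 with scan as a block, and of the 167 above the floor on all 4 arrays 10 were higher and 14 lower. The split was 12 and 9 under quantile normalization, 12 and 6 with a percentile over all miRNAs and 6 and 9 under normexp. Under normexp the values of miR-503, miR-9 and miR-9* were below 0, and miR-503 was at -0.78 with the total gene signal and with the deposited values. The count was 19 and 20 without the first and the second wild type untreated array, 19 and 21 without the first and the second knockout one, and 56 without either knockout array at 24 h.

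After 12 h of tunicamycin, miR-148a (-2.13, SE 0.33, limma adjusted p = 0.0112), miR-31* (-1.81, SE 0.13), miR-31 (-1.59, SE 0.13), miR-155 (-1.34, SE 0.21), miR-300 (-1.01, SE 0.21), miR-320 (-0.84, SE 0.18) and miR-22 (-0.71, SE 0.14) were lower in knockout than in wild type. miR-199b* (1.57, SE 0.21) was higher, though at -0.033 with the total gene signal and with the deposited values, and so was miR-361 (at least 2.19-fold, 1.58, SE 0.24), which turned to -0.49 under normexp. The miR-29 family had a median of 0.41 with 0 of 3 members past the threshold, and 2 higher adjusted over the list alone (camera adjusted p = 0.0493), and the Dlk1-Dio3 imprinted cluster had 3 of 16 members lower (median -0.49, adjusted p = 0.0493). Both calls were lost with an estimated correlation (adjusted p = 0.744 for each). The first was also lost in 6 of 13 alternatives and the second in 8 of 12, where its median ran from -0.78 to 0.00. In all 13 miRNAs passed, 4 higher and 9 lower, with 41 at an unadjusted p under 0.05 and 14 with scan as a block, and 9 of the 184 above the floor on all 4 arrays passed. The split was 5 and 2 under quantile normalization, 2 and 2 with a percentile over all miRNAs and 2 and 3 under normexp. The count was 8 and 5 without the first and the second knockout array at 12 h, 39 and 26 without the wild type ones, 28 without either wild type array at 24 h and 40 without either knockout array at 24 h.

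After 24 h of tunicamycin, miR-31* (-1.78, SE 0.13, limma adjusted p = 0.000424), miR-31 (-1.60, SE 0.13), miR-155 (-1.33, SE 0.21), miR-497 (-1.04, SE 0.23), miR-300 (-0.97, SE 0.21) and miR-320 (-0.86, SE 0.18) were lower in knockout. miR-196b (at least 8.77-fold, 3.29, SE 0.39), miR-199b* (2.22, SE 0.21), miR-322 (1.42, SE 0.32), miR-221 (1.12, SE 0.26) and miR-103 (0.96, SE 0.17) were higher, as was miR-652 (1.28, SE 0.17), which turned to -0.058 under normexp and to -0.32 with the total gene signal and the deposited values. The Dlk1-Dio3 imprinted cluster had 2 of 16 members lower (3 adjusted over the list alone, median -0.33, camera adjusted p = 0.0303, adjusted p = 0.706 with an estimated correlation). Over 12 alternatives its median ran from -1.08 to 0.00, and 7 lost the call. In all 20 passed, 12 higher and 8 lower, with 58 at an unadjusted p under 0.05 and 25 with scan as a block, and 14 of the 120 above the floor on all 4 arrays passed. The split was 11 and 3 under quantile normalization, 15 and 1 with a percentile over all miRNAs and 2 and 2 under normexp, where 1 of those miRNAs was among the 20. The count was 58 without the first and 38 without the second knockout array at 24 h.

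Over all conditions, the knockout arrays were compared with the wild type arrays to find differences held through the treatment. miR-31 (-1.62, SE 0.07, limma adjusted p = 9.48e-06), miR-31* (-1.75, SE 0.07) and miR-155 (-1.83, SE 0.12) were lower in knockout, and within each of the 4 scans and at each time miR-31 differed by between -1.51 and -1.74. miR-148a (-1.46, SE 0.19), miR-224 (-1.51, SE 0.16), miR-194 (-1.67, SE 0.41), miR-10a (-1.56, SE 0.43) and miR-99a (-1.54, SE 0.42) were lower too. Not all of these were seen in each condition. miR-194 was at the floor on all untreated arrays of both genotypes, and miR-224 was detected on no tunicamycin array. miR-99a was higher in knockout at 24 h within scan 4 (0.35). miR-196b (3.14, SE 0.22), miR-199b* (1.93, SE 0.12), miR-210 (1.36, SE 0.06), miR-361 (1.23, SE 0.14), miR-221 (1.18, SE 0.15) and miR-322 (1.03, SE 0.19) were higher, although miR-210 and miR-361 turned negative under normexp (-0.06 and -0.23). For miR-196b, miR-210 and miR-361, 2 of the groups had no array that detected the miRNA, so the size of the difference is uncertain. miR-221 and miR-222 (0.62, SE 0.11) share a cluster that targets cell-cycle inhibitors (camera adjusted p = 0.0799). Of the Dlk1-Dio3 imprinted cluster 5 of 16 members were lower (7 adjusted over the list alone, median -0.40, camera adjusted p = 0.0799).

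**Figure D3:**
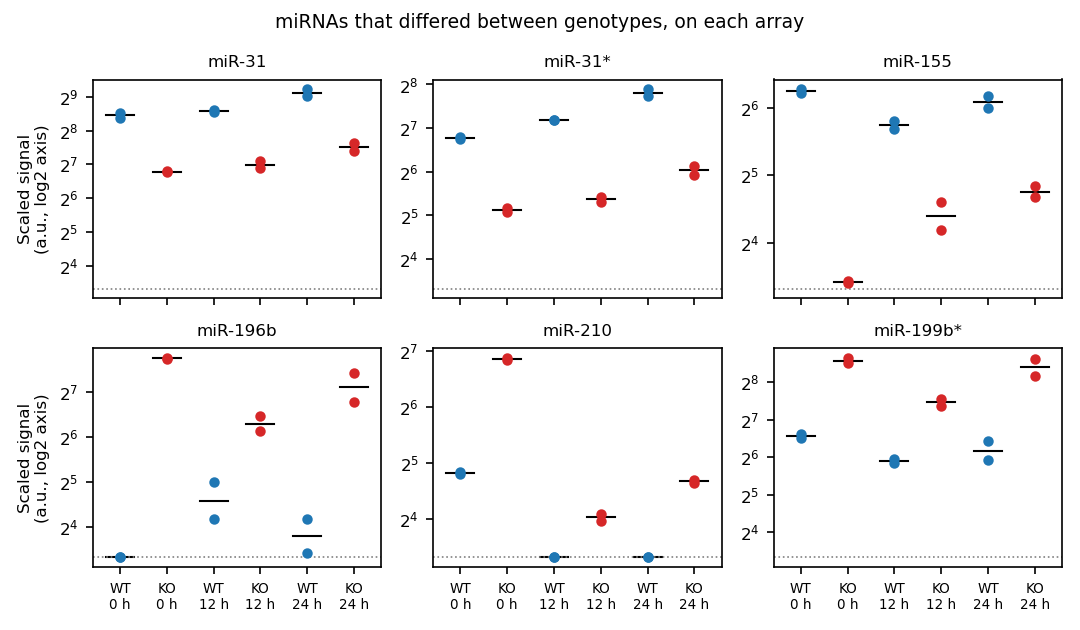
Scaled signal (arbitrary units, log2 axis) of 6 miRNAs that differed between genotypes on each array, wild type in blue and knockout in red, untreated (0 h), 12 h and 24 h. Points are arrays, black bars geometric means of 2 arrays and the dotted line the floor of 10.0. miR-31, miR-31* and miR-155 are lower and miR-196b and miR-199b* higher in knockout in each condition, as is miR-210, whose overall difference turns to -0.06 under normexp. At 12 h miR-199b* is at -0.033 with the total gene signal and with the deposited values.

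Over all conditions 59 miRNAs passed, 26 higher and 33 lower in knockout, with 93 at an unadjusted p under 0.05 and 46 with scan as a block, and 7 miRNAs passed in each of the 3 conditions. Of the 110 above the floor on all 12 arrays 17 were higher and 16 lower. The split was 23 and 11 under quantile normalization, 29 and 7 with a percentile over all miRNAs and 11 and 156 under normexp, which moved the median of all tested miRNAs by -0.38. The count was 37 and 35 without the first and the second wild type untreated array, 35 and 36 without the knockout ones, 39 and 37 without the first and the second knockout array at 12 h, and 89 without the second knockout array at 24 h. Wild type was always in row 1 and knockout in row 2, so genotype and array row cannot be told apart. Whether the replicates of a genotype came from separate cell isolates was not known here. A difference between isolates therefore cannot be told apart from the loss of XBP1 either.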

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

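The tests of floor values, scaling, slide and scan, and binding without a matching miRNA were chosen after the results were seen. No group had more than 2 arrays, so none was searched for an array far from the others.

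A difference between the genotypes' responses (wild type minus knockout) that passed limma's test brought 15 miRNAs here at 12 h. It was positive for miR-196b (2.70), miR-497 (2.22), miR-195 (2.01), miR-210 (1.31), miR-9* (1.24), miR-503 (1.23), miR-9 (1.17), miR-434-3p (0.91) and miR-30a (0.63). It was negative for miR-155 (-1.48), miR-335-5p (-1.46), miR-532-5p (-1.21), miR-290-5p (-1.20), miR-532-3p (-0.67) and miR-542-5p (-0.22). Of these, miR-335-5p, miR-532-5p, miR-290-5p and miR-542-5p turned positive under normexp, and miR-542-5p also under both other scalings and with outlier spots kept. With the total gene signal miR-155 (0.35) and miR-290-5p (1.45) turned positive and miR-503 negative (-0.78), and miR-155 turned with the deposited values too. The same test at 24 h brought miR-497 (2.22), miR-195 (1.72), miR-503 (1.23) and miR-9 (1.17) on the positive side. On the negative side were miR-155 (-1.49), miR-532-5p (-1.45), miR-152 (-1.40), miR-335-5p (-1.35), miR-374 (-0.82), miR-532-3p (-0.67) and miR-542-5p (-0.22). At 24 h miR-335-5p turned to 0.11 under normexp, miR-542-5p was positive under quantile normalization and a percentile over all miRNAs, and miR-503 was at -0.78 with the total gene signal. miR-337-5p (0.83), outside the rule for naming miRNAs, passed as well and was named after its value was seen.

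Of the 15 miRNAs at 12 h, 13 had a value at the floor, which gives dim groups no spread, and for 6 of them (miR-503, miR-532-5p, miR-532-3p, miR-542-5p, miR-9 and miR-9*) all 12 h arrays were at it, so that the value is the untreated genotype difference. With values at the floor left out, 0 miRNAs passed in limma and 12 of 149 had an unadjusted p under 0.05, but 2 of the 15 were still tested, so this test cannot tell the floor from a dependence on XBP1 for the other 13. Those 2, with no value at the floor on the 8 arrays, kept their values and lost the call. As their own values did not change, the loss came through the shared estimate of the spread and the set of p-values adjusted together. miR-30a (0.63) had an SE of 0.25 in place of 0.14 (limma adjusted p = 0.538). miR-155 (-1.48) had an SE of 0.29 in place of 0.30 (limma adjusted p = 0.117). The call of miR-155 thus depended on which other miRNAs were tested with it. For miR-497 and miR-195 only the knockout arrays at 12 h were at the floor. That limits the knockout fall and can lower the SE, but it cannot enlarge the positive difference. At 24 h miR-497 was above the floor on all 8 arrays, with 7 detecting it, and passed (2.22, limma adjusted p = 0.0103). Of the 15, 13 also differed between untreated knockout and wild type cells, so a genotype difference present before treatment stays open for them.

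Probes for 3 viral miRNAs, of viruses that no label names and outside the comparisons, gave more signal at 12 h than in untreated cells, while mcmv-miR-M23-1-5p had 17.4 and 18.9 untreated and -3.51 and 3.42 at 12 h. The mean unscaled signal of mghv-miR-M1-2, of a gammaherpesvirus, was 323 (SD 15.6) in wild type and 335 (SD 73.6) in knockout. Untreated it was 86.3 (SD 68.4) and 100.3 (SD 83.2), and at 24 h 54.1 and 48.5. For mghv-miR-M1-6 it was 44.0 (SD 35.3) and 52.2 (SD 24.2), against 11.2 and 6.42 untreated and 8.60 and 8.98 at 24 h. That of mcmv-miR-m59-2 was 10.0 (SD 12.5) in wild type at 12 h, where 1 of 2 arrays detected it, against -3.75 untreated.

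The transient rise of the Sfmbt2 cluster was weighed against 3 technical explanations. Scaling between arrays is argued against as the whole cause, since before scaling the median log2 ratio of 12 h over untreated was 2.35 in wild type and 2.22 in knockout. For the fall from 12 h to 24 h, slide or scan is argued against too, since those arrays shared both and the median within a scan was -3.70 and -2.33. Array column is not covered by this, as it went together with time. Nor is the rise from untreated, where slide went together with treatment. Without tunicamycin, some members varied between untreated arrays, which lay in different scans. The log2 SD in wild type and knockout was 1.12 and 0.504 for miR-467b* and 0.965 and 0.495 for miR-466i. It was 0.0884 and 0.0511 for miR-467a*, and members at the floor on all untreated arrays had none. The cause of this spread was not tested. Labelled RNA that binds probes without a matching miRNA may account for part of the rise. Before scaling, 2 viral miRNAs, mghv-miR-M1-2 and mghv-miR-M1-6, were over 2-fold above untreated and 24 h means in both genotypes. The unscaled signal of mcmv-miR-M23-1-5p fell, but the total signal was lower on every tunicamycin array too, so that fall decides nothing here. Uneven labelling between arrays was not tested. The labelling controls dmr31a and dmr285 are given as log10 signals in wild type and knockout. In scan 4 dmr31a was 3.182 and 3.232 at 12 h, against 1.499 and 1.517 at 24 h. There dmr285 was 2.75 and 2.78, against 2.82 and 2.84. In scan 3 dmr31a was 1.723 and 1.834 at 12 h, against 1.569 and 1.935 at 24 h. There dmr285 was 2.993 and 2.047, against 1.895 and 2.228. Uneven labelling, binding without a matching miRNA and a response of the cluster to tunicamycin stay open, as does slide or scan for the rise from untreated. The same holds for the other miRNAs that rose at 12 h and were lower at 24 h.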

How the results depend on the processing

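The alternatives that left values at the floor out, used the floor as a pseudocount, kept outlier spots, left the 12 h arrays out or crossed the replicate numbers were chosen after seeing the data, the others before the data were examined. Of 172 counts of miRNAs under an alternative other than leaving out 1 array, 118 stayed within 1.5 times the count in the report and 54 did not. Of 2678 values of named miRNAs, 2062 kept their direction and side of the threshold, 540 kept direction and lost the call, and 76 changed sign. Of 203 medians of lists, 143 kept the call, 55 lost it in the same direction and 5 changed sign. The values of the other sign listed below cover the miRNAs with the largest rises and falls of a comparison and the lists that passed camera there. Changes of sign of other miRNAs and lists, such as miR-96, are given elsewhere in the text. Where no reason is given below, the cause was not tested. The comparisons are named by time and genotype, with XBP1 dependence for wild type minus knockout response and genotype for knockout minus wild type.

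With normexp background correction, the count changed by over 1.5 times, to 6 in the 12 h XBP1 dependence, 191 in the 24 h wild type, 188 in the 24 h knockout, 2 in the 24 h XBP1 dependence, 49 in the 24 h against 12 h, 15 in the untreated genotype, 5 in the 12 h genotype, 4 in the 24 h genotype and 167 in the all-condition genotype. 12 h wild type values of the other sign were 0.61 for miR-361, 0.65 for miR-152, 0.76 for miR-146a, 1.03 for miR-362-5p, 0.24 for miR-378, 0.50 for miR-467a, 0.97 for miR-101a and 0.85 for miR-362-3p. 12 h knockout values of the other sign were 0.10 for miR-497, 0.24 for miR-195, 0.36 for miR-467a, 0.40 for miR-152, 0.49 for miR-218, 0.46 for miR-503, 0.11 for the miR-30 family list (median) and 1.03 for the cluster of miR-322 and miR-503 (median). 12 h XBP1 dependence values of the other sign were 0.34 for miR-335-5p, 0.28 for miR-532-5p, 0.063 for miR-290-5p and 0.15 for miR-542-5p. 24 h wild type values of the other sign were 0.16 for miR-378, 0.61 for miR-152, 0.67 for miR-146a, 0.61 for miR-361, 0.48 for miR-467a, 1.06 for miR-210, 0.76 for miR-143 and 1.30 for the cluster of miR-322 and miR-503 (median). 24 h knockout values of the other sign were 0.43 for miR-195, 0.33 for miR-497, 0.25 for miR-146a, 0.018 for miR-378, 0.68 for miR-503, 0.62 for miR-467a and 1.27 for the cluster of miR-322 and miR-503 (median). 24 h XBP1 dependence values of the other sign were 0.11 for miR-335-5p. Untreated genotype values of the other sign were -0.050 for miR-9*, -0.0034 for miR-503 and -0.071 for miR-9. 12 h genotype values of the other sign were -0.49 for miR-361 and -0.61 for miR-210. 24 h genotype values of the other sign were -0.20 for miR-361, -0.33 for miR-210, -0.058 for miR-652, -0.39 for miR-152 and -0.39 for miR-374. Genotype over all conditions values of the other sign were -0.059 for miR-210, -0.23 for miR-361, -0.15 for miR-342-3p, -0.24 for miR-193b, -0.16 for miR-143 and -0.17 for miR-652. By construction normexp adds an offset of 50 to every spot, which weighs more on arrays with little signal, and the scale factors ran from 0.318 on untreated to 3.78 on tunicamycin arrays. It moved the median of all tested miRNAs by 1.32 in wild type and 0.89 in knockout at 12 h, by 1.16 and 1.08 at 24 h, and by -0.38 between genotypes over all conditions. How much of each change this explains was not tested.

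With quantile normalization, the count changed by over 1.5 times, to 21 in the untreated genotype, 7 in the 12 h genotype and 34 in the all-condition genotype. 12 h XBP1 dependence values of the other sign were 0.088 for miR-542-5p. 24 h XBP1 dependence values of the other sign were 0.088 for miR-542-5p. It moved the median of all tested miRNAs by -0.63 in wild type and -0.54 in knockout at 12 h and by 0.43 between 24 h and 12 h.

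With the percentile taken over all mouse miRNAs, the count changed by over 1.5 times, to 8 in the 12 h XBP1 dependence, 16 in the 24 h wild type, 16 in the 24 h knockout, 18 in the untreated genotype, 4 in the 12 h genotype and 36 in the all-condition genotype. 12 h XBP1 dependence values of the other sign were 0.17 for miR-542-5p. 24 h XBP1 dependence values of the other sign were 0.17 for miR-542-5p. It moved the median by -0.46, -0.56 and 0.45 in those 3 comparisons.

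With the array software's total gene signal, the count changed by over 1.5 times, to 26 in the 12 h XBP1 dependence, 59 in the 24 h knockout, 24 in the 24 h XBP1 dependence and 26 in the 12 h genotype. 12 h wild type values of the other sign were 0.22 for miR-146b. 12 h XBP1 dependence values of the other sign were -0.78 for miR-503, 0.35 for miR-155 and 1.45 for miR-290-5p. 24 h knockout values of the other sign were 1.57 for miR-467a. 24 h XBP1 dependence values of the other sign were -0.78 for miR-503. 24 h against 12 h values of the other sign were -1.48 for miR-100 and -0.63 for miR-29c. Untreated genotype values of the other sign were -0.78 for miR-503. 12 h genotype values of the other sign were -0.033 for miR-199b*. 24 h genotype values of the other sign were -0.32 for miR-652.

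With the mean of the probes' log2 values, the count changed by over 1.5 times, to 2 in the 12 h XBP1 dependence, 1 in the 24 h XBP1 dependence and 8 in the 12 h genotype.

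With no filter on dim miRNAs, the count changed by over 1.5 times, to 6 in the 12 h XBP1 dependence, 23 in the 24 h knockout, 7 in the 24 h XBP1 dependence, 13 in the 24 h genotype and 28 in the all-condition genotype.

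With only miRNAs detected on all 12 arrays, the count changed by over 1.5 times, to 40 in the 12 h wild type, 48 in the 12 h knockout, 1 in the 12 h XBP1 dependence, 17 in the 24 h wild type, 15 in the 24 h knockout, 1 in the 24 h XBP1 dependence, 59 in the 24 h against 12 h, 11 in the untreated genotype and 36 in the all-condition genotype. 12 h wild type values of the other sign were -0.040 for the passenger strands list (median). Fewer miRNAs were tested there by construction.

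With the floor at the 25th percentile, the count changed by over 1.5 times, to 9 in the 12 h XBP1 dependence, 8 in the 12 h genotype and 12 in the 24 h genotype.

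With the authors' deposited log2 values, the count changed by over 1.5 times, to 81 in the 12 h wild type, 63 in the 24 h knockout, 72 in the 24 h against 12 h, 23 in the 12 h genotype and 35 in the 24 h genotype. 12 h wild type values of the other sign were 0.22 for miR-146b and 0.77 for miR-362-5p. 12 h XBP1 dependence values of the other sign were 0.35 for miR-155. 24 h wild type values of the other sign were 0.27 for miR-146b and 0.93 for miR-467a. 24 h knockout values of the other sign were 1.57 for miR-467a. 24 h against 12 h values of the other sign were -1.48 for miR-100. Untreated genotype values of the other sign were -0.78 for miR-503. 12 h genotype values of the other sign were -0.033 for miR-199b*. 24 h genotype values of the other sign were -0.32 for miR-652. Genotype over all conditions values of the other sign were -0.55 for miR-342-3p and 0.21 for miR-130b.

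With values at the floor left out, the count changed by over 1.5 times, to 79 in the 12 h wild type, 81 in the 12 h knockout, 0 in the 12 h XBP1 dependence, 3 in the 24 h XBP1 dependence and 11 in the 24 h genotype. Here too fewer miRNAs were tested, 149 of 256 for the 12 h XBP1 dependence.

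With the floor as a pseudocount, the count changed by over 1.5 times, to 8 in the 12 h XBP1 dependence.

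With outlier spots kept, no count changed by over 1.5 times. 12 h XBP1 dependence values of the other sign were 0.052 for miR-542-5p.

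With the 12 h arrays left out, the count changed by over 1.5 times, to 3 in the 24 h XBP1 dependence. Fewer arrays entered that fit.

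With a block for replicate number no count changed by over 1.5 times, and of 204 values of named miRNAs and lists 193 kept the call, 11 lost it and 0 changed sign. The counts were then 130 and 127 at 12 h, 45 and 33 at 24 h, 12 and 13 for XBP1 dependence, 114 between 24 h and 12 h, and 31, 15, 19 and 53 for genotype. Pairing the 24 h arrays crosswise gave 43 and 30 there, and 29 of 34 values kept the call. Counts with scan as a block, without an intensity trend and with outlier spots kept also stayed within 1.5 times.

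With 1 array left out, where the lone array of a group was assumed to vary like the other groups, 91 of 132 counts stayed within 1.5 times, and 1870 of 2256 values of named miRNAs kept their call, 386 lost it and 0 changed sign. The 12 h counts ran from 85 (second untreated wild type array out) to 148 in wild type and from 86 to 144 in knockout. XBP1 dependence at 12 h ran from 5 (first 12 h knockout array out) to 31 (first 12 h wild type array), with 23 without either 24 h knockout array. The 24 h wild type count ran from 24 to 77, with 26 and 24 without the untreated wild type arrays and 75 and 77 without the 24 h knockout arrays. In knockout it ran from 17 to 63, with 17 and 19 without the untreated knockout arrays and 63 and 57 without the 24 h ones. XBP1 dependence at 24 h ran from 7 without either 12 h knockout array to 44 and 20 without the 24 h ones. Between 24 h and 12 h the count ran from 78 (second 12 h knockout array out) to 137. Untreated genotype counts ran from 19 to 56, with 19 and 20 without the wild type arrays, 19 and 21 without the knockout ones and 56 without either 24 h knockout array. Genotype counts at 12 h ran from 5 to 40, with 39 and 26 without the 12 h wild type arrays, 8 and 5 without the knockout ones, 28 without either 24 h wild type array and 40 without either 24 h knockout array. At 24 h they ran from 16 to 58, with 58 and 38 without the 24 h knockout arrays. Over all conditions they ran from 35 to 89, with 37 and 35 without the untreated wild type arrays, 35 and 36 without the knockout ones, 39 and 37 without the 12 h knockout arrays and 89 without the second 24 h knockout array.

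Signal over background limits the dim miRNAs, since between 44 and 103 of the 256 tested miRNAs lay at the floor on an array.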

Other observations

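The counts of 100 and 35 splits were planned, and the count within pairs and the test of array row were chosen after the results were seen. The miRNAs named in this part were chosen after their values were seen.

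A few single miRNAs rose at 12 h in both genotypes and were lower at 24 h, while the lists that hold them did not pass at 12 h. Camera gave adjusted p = 0.524 in wild type and 0.0967 in knockout for the cluster of miR-290 to miR-295, 0.450 and 0.723 for Hox-cluster miRNAs and 0.868 and 0.856 for the miR-34 family, and muscle markers had 1 tested member. miR-206, the sole tested muscle marker, was at least 5.81-fold higher in wild type (2.54, SE 0.46, limma adjusted p = 0.00377) and 2.75 (SE 0.46) above the floor in knockout, and it was at the floor untreated and at 24 h, so that the floor limits both sizes. miR-294, of a cluster active in pluripotent cells, was at least 15.4-fold and 12.1-fold higher (3.95 and 3.60, SE 0.49), while miR-290-5p of that cluster fell in wild type (-0.85, SE 0.14), a value that turned to 1.43 under normexp. miR-615-3p, from a Hox cluster, was at least 9.28-fold and 6.67-fold higher (3.21 and 2.74, SE 0.39). miR-34b-3p was at least 9.56-fold and 9.20-fold higher (3.26 and 3.20, SE 0.42), while miR-34a differed by 0.05 and -0.36 (SE 0.31). The rises of miR-206, miR-294, miR-615-3p and miR-34b-3p and their falls to 24 h kept their sign under normexp, quantile normalization and a percentile over all miRNAs. For the rises normexp is little support. It moved the median of all tested miRNAs up by 1.32 in wild type and 0.89 in knockout at 12 h. The falls were smaller under normexp, at -0.29, -0.34, -0.18 and -0.47. As 2 viral probes had the same course, binding without a matching miRNA may also account for these rises, which was not tested.

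Before scaling, a viral probe went the other way, on tunicamycin arrays whose total signal was lower as well. mcmv-miR-M23-1-5p, of a cytomegalovirus, was detected on both untreated arrays of each genotype, at a mean unscaled signal of 17.4 (SD 2.93) in wild type and 18.9 (SD 1.07) in knockout, and on none of the tunicamycin arrays.

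Other groupings of the arrays were counted in a simpler model. For knockout against wild type over all conditions, 1 of 100 drawn splits, the real one, gave as many miRNAs as the real 38, and the highest other gave 17, which argues against a chance split. Of all 32 splits that part the 6 pairs of arrays of 1 time and replicate number, which differ in the pairs whose genotypes are exchanged, again 1, the real one, gave as many. The highest other gave 17. The smallest share that 32 splits can give is 1 of 32, so a chance split within pairs is argued against but not excluded. Array row cannot be told apart from genotype, since the 2 went together on 12 of 12 arrays. Nor can a difference between cell isolates, as the isolates behind the replicates were not known here. For 24 h against 12 h, 1 of 35 splits gave as many as the real 80. The highest other gave 11, from the split by genotype. Here 1 of 35 is the smallest share possible, so chance is argued against but not excluded. Array column cannot be told apart from time in this comparison.

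The array software's total gene signal did not follow the summed probe signal by a fixed factor. Among 234 tested miRNAs detected above the floor on at least 2 arrays, the ratio of total to sum changed over 2-fold between arrays for 128 and over 4-fold for 101. Relative to the array's median, that ratio was 1 at the median where all probes of a miRNA were well above background and 4.64 where under 50 percent were. For let-7d* on the first wild type arrays, the sum was 18.2 untreated and 101.5 at 12 h, while the total was 696 and 33.5.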
